A study of Mus musculus with 15 samples.

How the data were processed

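RNA was measured by sequencing in 15 libraries of mouse T helper 2 (Th2) cells made in culture from naive splenic CD4+ T cells of female mice. Per the labels' protocols, cells were grown for 3 days on anti-CD3ε at 5 µg/ml with interleukin 2 at 10 ng/ml, interleukin 4 at 40 ng/ml, anti-CD28 at 1 µg/ml and anti-interferon gamma at 10 µg/ml. They were then kept for 3 days in medium with both interleukins at 20 ng/ml and no antibodies. Stimulated cells received plate-coated anti-CD3ε at 3 µg/ml and soluble anti-CD28 at 2 µg/ml from day 5 for 24 h. Per the labels' protocols, libraries came from a stranded total RNA kit with depletion of ribosomal RNA, so RNAs without a poly(A) tail are also present.

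Each library had an estimated count and a length-scaled TPM value for each of 56748 genes. The estimated counts were deposited without scaling between samples, and not all were whole numbers. The TPM values are the authors' own, scaled within each library. Per the submitters' processing notes, cutadapt 3.4, STAR 2.7.9a, Salmon 1.10.1 and the GRCm39 genome were used, without the role of each tool or the annotation release. No other processing step is recorded in the labels. Gene names were used as the tables pair them with Ensembl identifiers.

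Everything below was computed from those tables with R 4.3.3. Estimated counts were rounded to whole numbers. Genes were kept when edgeR 4.0.16 found enough counts for the group sizes (filterByExpr), which left 15619 genes holding at least 99.9% of the counts of every library; 28643 genes had no count in any library. Libraries were scaled by the trimmed mean of M-values. A quasi-likelihood model with 1 mean per group and robust dispersion was fitted to all 15 libraries, and each comparison was tested two-sided with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes come from the same model. Values per group are CPM on the scaled library sizes, given as mean ± SD over libraries, with n = 3 for non-stimulated control, 5 for stimulated control, 3 for non-stimulated cKO and 4 for stimulated cKO unless stated otherwise. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these libraries.

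The 4 groups gave 5 comparisons: stimulated against non-stimulated within each genotype, cKO against control within each condition, and the difference between the 2 stimulation responses (interaction). Library totals ran from 17.1 to 24.2 M estimated counts, and the biological coefficient of variation was 15.4%. Intervals and floors from counts cover counting error only, because reads without molecular identifiers are not independent molecules. A group whose libraries all had 0 counts was given a floor of 3 counts over the summed library sizes of the group. Folds with 1 to 3 counts in a group are ratios of summed counts with an exact 95% binomial interval. Single-gene comparisons of groups used two-sided exact permutation tests.

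There were 20 gene lists for pathways and cell programs and 12 lists of cell type markers, with 411 genes, of which 410 had a row in the tables and 339 were tested. Lists with at least 3 tested genes, 27 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with adjustment over the lists of each comparison. Alternatives for lists were a correlation estimated from the data, fry, and a block for the replicate number. Members of a list were also counted when adjusted over the list alone. A further 20 gene families, defined by gene symbol, were chosen after the data were seen and tested in the same way.

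Genes named in the text follow a rule. It takes Asb2, the filamin gene Flna, and Gata3, Il4, Il5 and Il13 in every comparison. It takes the 10 largest rises and 10 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the groups. From each gene list it takes the 4 members with the smallest p. Names that are only clone identifiers, mitochondrial and small RNA genes, pseudogenes and variable segments were left out of the rises and falls. Some genes that the rule takes are not reported here. Any other gene named, apart from Xist as a check of sex, was chosen after its values were seen; these are the most abundant markers of cell types, genes called only under an alternative, members of gene families and a neighbour of Asb2. The comparisons, tests, gene lists, this rule and the alternatives not described as added later were fixed before the data were examined.

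Alternatives were DESeq2 1.42.0; relative log expression size factors; no filter on low counts; a filter of 1 CPM in 3 libraries; only the groups compared; the replicate number as a block, alone or within genotype; no robust dispersion; limma-voom with sample quality weights; limma on log2 of TPM plus 0.1 or plus 1; leaving out small RNA, mitochondrial and histone genes; 1 surrogate variable from sva 3.50.0; and leaving out each library in turn. A 7SL RNA covariate, and leaving out the 2 libraries farthest out on the second principal component, were added after the data were seen. Whether equal replicate numbers pair libraries across groups was not settled. In 4 of the 15 libraries the best match carried the same number. Correlations over genes between libraries of the same number, with group means removed, ran from -0.262 to 0.266. Those of replicate 1 were all positive, as were those between non-stimulated and stimulated cKO cells. The replicate block is therefore given among the alternatives. For 7SL RNA, the bounds under which library size and genotype count as argued against were made stricter after the values were seen.

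The scripts were tested on simulated counts drawn for the real genes from the means and sizes of the real libraries. In simulated data at the real group sizes, the test recovered 75.1% of 2-fold changes between genotypes without stimulation and 84.1% after it. These are shares of 201 genes given such a change, pooled over several simulated sets of the 15619 tested genes. Each set held many changed genes at once, which makes the adjusted threshold easier to pass than in a comparison with 0 or 1 call. The draws also left out variation shared by the genes of a library. The shares are thus likely too high for the real genotype comparisons. For changes of 1.5-fold the shares were 33.3% and 52.2%, and for 4-fold changes 97.5% and 98.5% (201 and 198 genes given each change). For stimulation, 2-fold changes were recovered in 76.6% of cases in control cells and 74.6% in cKO cells. Neighbouring genes of Asb2 were taken from a RefSeq table of the GRCm38 assembly, which is not the build of the counts, so that only the order of genes was used and no coordinate is given; 13697 tested genes matched it by name.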

Results

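The series asked how loss of ASB2 alters the RNA of Th2 cells at rest and after renewed stimulation of the T cell receptor. ASB2 is the substrate-recognition subunit of an E3 ubiquitin ligase whose known substrates include the actin-binding filamins. Control cells carried floxed Asb2 alleles alone. Conditional knockout (cKO) cells carried the same alleles with Cre recombinase under the VE-cadherin promoter, which is active in endothelium and in precursors of blood cells. Cells were left without a further stimulus or were stimulated for 24 h with anti-CD3ε and anti-CD28, giving 3 non-stimulated control, 5 stimulated control, 3 non-stimulated cKO and 4 stimulated cKO libraries.

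Estimated counts totalled 18.8, 18.9 and 23.5 M in replicates 1 to 3 of non-stimulated control cells. The totals of the 5 stimulated control libraries were 18.7, 19.7, 20.4, 17.9 and 17.1 M. Those of the non-stimulated cKO libraries were 18.9, 18.4 and 21.5 M, and those of the stimulated cKO libraries 21.0, 24.2, 17.2 and 18.2 M. The first principal component of log2 CPM held 65.7% of the variance and placed all 6 non-stimulated libraries on one side and all 9 stimulated libraries on the other. On the second component, with 5.06%, stimulated cKO replicate 3 (score 33.1) and non-stimulated control replicate 3 (23.7) had the highest scores. In stimulated cKO replicate 3, mitochondrially encoded RNA took 9.43% of counts, against 4.36% to 6.24% in the other 14 libraries. Xist was at 4168 CPM or more in each library, and 4 Y-linked genes together had at most 1 count.

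The targeted gene, Asb2 (ENSMUSG00000021200), was called lower in cKO than in control cells after stimulation but not without it, and its RNA was still detected in each cKO library. After stimulation Asb2 was at 9.49 ± 0.115 CPM in cKO cells (n = 4, range 9.36 to 9.59) and at 33.5 ± 2.72 CPM in control cells (n = 5, range 31.2 to 38.0), so that 28.3% of the control level remained. The log2 fold change was -1.82 ± 0.18 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.4e-04), and the exact permutation p of 0.00794 was the smallest that 4 against 5 libraries can give. Without stimulation the level was 19.2 ± 5.62 CPM in cKO cells (n = 3) and 36.7 ± 12.2 CPM in control cells (n = 3), and all 3 cKO libraries lay below all 3 control libraries. That log2 fold change of -0.94 ± 0.21 had an unadjusted p of 3.3e-04 and was not called by edgeR (adjusted p = 1). With DESeq2 it was -0.94 with an adjusted p of 0.0526, also not called. The edgeR adjusted p was 0.205 without non-stimulated control replicate 2. The adjustment was over all genes tested, although Asb2 was named beforehand. The exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. The labels do not say which exons are flanked by loxP sites, so reads from undeleted exons count towards these levels.

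**Figure D1:**
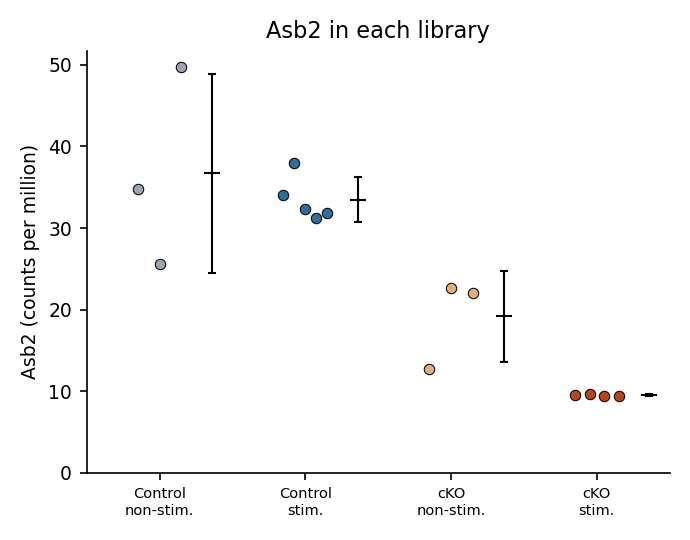
Asb2 in CPM in each library (points) of the 4 groups, with mean and SD (bars; n = 3, 5, 3 and 4). The 4 stimulated cKO libraries lie between 9.36 and 9.59, below the 5 stimulated control libraries at 31.2 to 38.0.

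Stimulation of control cells was compared first, as the response of Th2 cells with intact Asb2. Genes of the Th2 cytokines rose. Il5, which supports eosinophils, went from 3.43 ± 1.00 to 1035 ± 136 CPM, a log2 fold change of 8.22 ± 0.29. Il13 went from 26.5 ± 14.2 to 1726 ± 176 CPM (6.02 ± 0.42) and Il4 from 10.4 ± 4.44 to 115 ± 21.3 CPM (3.45 ± 0.34). Gata3, the transcription factor that specifies Th2 cells, was at 701 ± 38.5 CPM before and 721 ± 35.9 CPM after stimulation and was not called (edgeR adjusted p = 0.77). In all, 7897 of 15619 genes were called, 3961 higher and 3936 lower, with changes of at least 2-fold in 1222 and 1578 of them. On the TPM scale with 0.1 added, where the median of all genes moved up by 0.14 on the log2 scale, the counts were 3754 higher and 2108 lower.

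The 24 measured genes of the cytokine and chemokine list all rose in control cells, with a median log2 fold change of 4.11, unchanged with genes at 0 counts set to their floor (camera adjusted p = 1.0e-25, and adjusted p = 9.2e-04 with an estimated correlation). Il21, Lif and Tnfsf11, the last of which encodes the ligand of RANK, rose by 6.98 ± 0.38, 3.21 ± 0.17 and 2.93 ± 0.20. Il1a, Il3 and Il2 had 0 counts in all 3 non-stimulated control libraries and reached 34.6 ± 4.83, 30.3 ± 9.56 and 9.03 ± 5.59 CPM, which was at least 706-fold, 617-fold and 184-fold higher than a floor of 3 counts over the group.

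Of 24 measured genes of T cell receptor activation, 19 rose and 1 fell, with a median of 1.59. The camera adjusted p was 4.1e-13, and the adjusted p was 0.11 with an estimated correlation. Among them were the transcription factor genes Egr3 (3.66 ± 0.16), Bhlhe40 (2.17 ± 0.16) and Fos (2.73 ± 0.22) and the co-stimulatory ligand gene Cd40lg (2.06 ± 0.14). Of 12 inhibitory receptor genes 8 rose and 3 fell, with a median of 1.42 (camera adjusted p = 7.0e-06; adjusted p = 0.11 with an estimated correlation). Cd200, which encodes a surface ligand, rose by 5.01 ± 0.19, Btla by 2.89 ± 0.18, Lag3 by 2.32 ± 0.18 and Pdcd1, the gene of PD-1, by 2.00 ± 0.15.

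The other T helper programs held members that moved in both directions. In the Th2 list of 15 measured genes 8 rose and 5 fell (camera adjusted p = 0.024, but adjusted p = 0.66 with an estimated correlation). The falling members included the interleukin 25 receptor gene Il17rb (-5.21 ± 0.49, to 0.121 ± 0.117 CPM) and Il4ra (-1.11 ± 0.11). In the Th1 list 4 rose and 5 fell of 12. Ifng, the gene of interferon gamma, rose by 6.40 ± 0.88, while Eomes and Stat4, transcription factors of Th1 cells, fell with log2 fold changes of -3.21 ± 0.47 and -1.01 ± 0.19. Of 6 Th17 genes 4 rose and 1 fell, and Il17a rose from 0.0611 ± 0.0652 to 4.91 ± 4.30 CPM. Of 10 genes of regulatory T cells 6 rose, among them Gpr83 (2.10 ± 0.19) and Nrp1 (2.34 ± 0.26), and 2 fell, among them Lrrc32 (-2.26 ± 0.22). Of 9 follicular helper genes 4 rose and 3 fell (camera adjusted p = 0.020; adjusted p = 0.11 with an estimated correlation), with lower Sh2d1a (-0.86 ± 0.11), which encodes an adaptor for help to B cells. The camera adjusted p was 0.81 for Th1, 0.14 for Th17 and 0.14 for regulatory T cell genes.

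**Figure D2:**
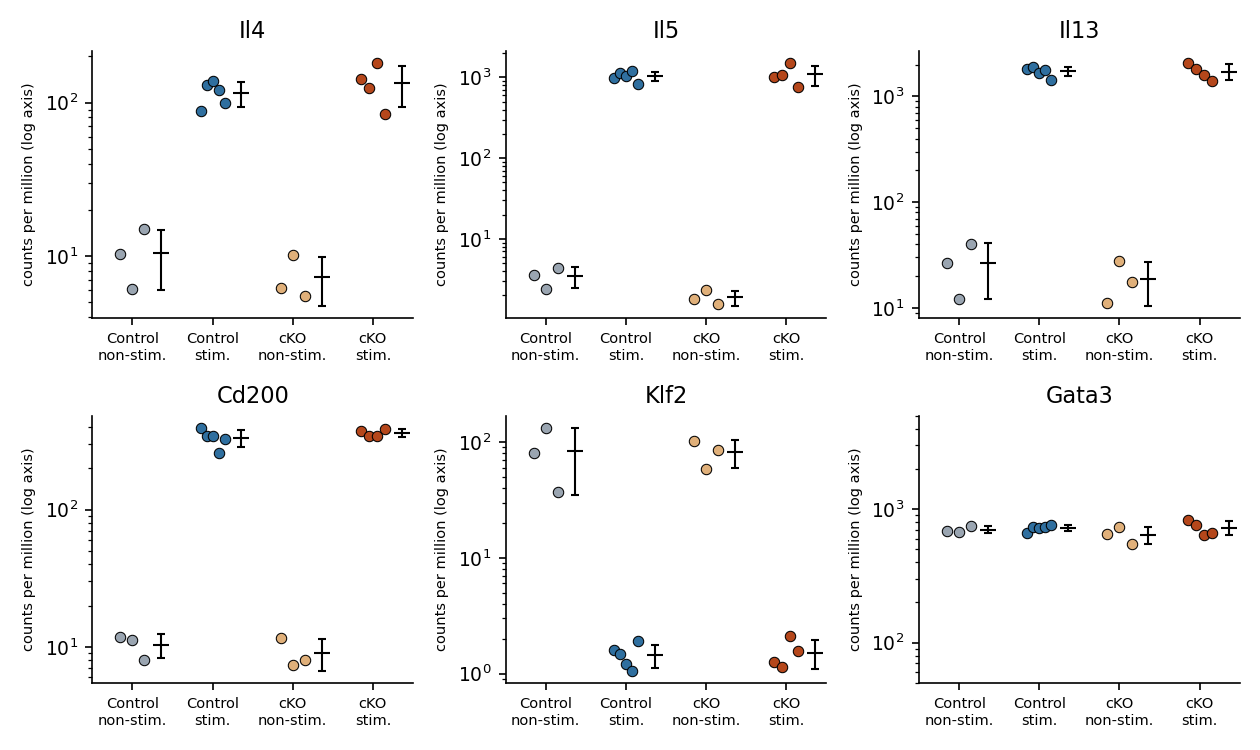
CPM on a log axis for 6 genes in each library (points) of the 4 groups, with mean and SD (bars; n = 3, 5, 3 and 4). Il4, Il5, Il13 and Cd200 are higher and Klf2 is lower in all stimulated libraries of both genotypes, while the values of Gata3 overlap between the groups.

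Genes of quiescence and lymph node homing fell more often than they rose in control cells, 9 against 2 of 15, with a median of -0.77 (camera adjusted p = 5.6e-04; adjusted p = 0.19 with an estimated correlation). Klf2, a transcription factor that keeps T cells quiescent, dropped from 83.1 ± 48.1 to 1.45 ± 0.334 CPM (-5.84 ± 0.38), and Pdcd4, Btg2 and Lef1 changed by -1.43 ± 0.12, -1.16 ± 0.10 and -0.79 ± 0.08. Proliferation genes were lower too: 12 of 22 cell cycle genes fell and none rose, with a median of -0.33 (camera adjusted p = 0.0063; adjusted p = 0.67 with an estimated correlation). Mki67 changed from 2762 ± 436 to 1586 ± 157 CPM (-0.80 ± 0.11), Birc5 by -0.92 ± 0.12, Top2a by -0.66 ± 0.11 and the replication gene Mcm6 by -0.65 ± 0.08.

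Among protein-folding and amino acid genes, more rose than fell after stimulation of control cells. In the list of the unfolded protein response 9 of 15 genes rose and none fell (median 0.37; camera adjusted p = 0.0031; adjusted p = 0.53 with an estimated correlation), among them the chaperone genes Hspa5 (1.32 ± 0.21) and Calr (0.95 ± 0.10) and the disulfide isomerase gene Pdia6 (1.39 ± 0.11). In the ATF4 and amino acid list 13 of 15 rose and 1 fell (median 0.62; camera adjusted p = 0.0026; adjusted p = 0.62 with an estimated correlation), with higher Asns (1.18 ± 0.15), which encodes asparagine synthetase, Sesn2 (1.19 ± 0.15) and Mthfd2 (0.85 ± 0.10) and lower Ddit4 (-0.60 ± 0.07). Glycolysis genes were mixed, with 3 higher and 4 lower of 15 (camera adjusted p = 0.81): the hexokinase gene Hk2 (1.81 ± 0.14) and glucose transporter gene Slc2a1 (0.66 ± 0.12) rose, and Gpi1 (-0.78 ± 0.10) and Slc2a3 (-0.85 ± 0.15) fell. Of 18 sterol synthesis genes 7 fell and none rose (camera adjusted p = 0.12), including Sc5d (-0.88 ± 0.12) and Insig1 (-0.59 ± 0.12).

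The remaining pathway lists had smaller or mixed changes in control cells. Of 25 filamin, actin and adhesion genes 13 fell and 1 rose (median -0.37; camera adjusted p = 0.0019; adjusted p = 0.45 with an estimated correlation). Flna, the gene of filamin A, changed from 816 ± 155 to 528 ± 60.2 CPM (-0.63 ± 0.13), and Tln1, Coro1a and Was, which act on integrins and actin, changed by -0.83 ± 0.10, -1.09 ± 0.14 and -1.06 ± 0.09. Of 13 genes of the ASB2 ligase and its substrates 6 rose, including Jak2 (0.79 ± 0.10) and Cul5 (0.55 ± 0.11), and 2 fell (camera adjusted p = 0.53). Of 18 p53 and apoptosis genes 7 rose and 5 fell (camera adjusted p = 0.49), with lower Bcl2l11 (-2.72 ± 0.17), which promotes apoptosis, and higher Bcl2l1 (1.88 ± 0.19), which opposes it, and Mdm2 (0.70 ± 0.10). Of 12 hypoxia genes 5 rose and 3 fell (camera adjusted p = 0.81), with higher Ero1a (1.27 ± 0.15) and Vegfa (1.08 ± 0.11) and lower Kdm3a (-1.56 ± 0.11). Of 13 interferon response genes 2 rose and 4 fell (camera adjusted p = 0.79), with lower Mx1 (-2.15 ± 0.26). None of 13 mitochondrially encoded genes was called (camera adjusted p = 0.49).

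Among called genes the 10 largest rises in control cells also included Pdpn, which encodes podoplanin, with 0 counts before stimulation and 11.5 ± 7.32 CPM after it (at least 234-fold higher than the floor). Crabp2, a retinoic acid binding protein gene, the chemokine gene Ccl9 and the parathyroid hormone gene Pth rose by 8.93 ± 0.66, 8.36 ± 0.64 and 8.11 ± 0.48. Slc7a2, which encodes a transporter of cationic amino acids, and Pla2g4e, which encodes a phospholipase, each had 3 counts before stimulation, and their summed counts rose 277-fold (95% interval 94.7 to 1347) and 159-fold (54.1 to 771). The keratin gene Krt80 fell 287-fold (95% interval 78.9 to 2377, with 2 counts left). Ica1l (-5.46 ± 0.45), Igsf5 (-5.33 ± 0.52), Rap1gap2 (-5.29 ± 0.61), Nhsl2 (-5.02 ± 0.47), Gucy2e (-4.73 ± 0.24), Pcyt1b (-4.60 ± 0.21) and Rnf144a (-4.30 ± 0.32) also fell. The change of Ifi203 (-5.81 ± 0.47) is uncertain, since the gene belongs to a family of near-identical copies that can share reads.

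Stimulation of cKO cells gave a response with much the same genes. Of the 3961 genes that rose in control cells 3416 also rose in cKO cells (1058 if the calls were independent), and of 3936 that fell 3373 also fell (1065 if independent), while 5 genes were called in opposite directions. Across the 15619 genes, which are not independent replicates, the log2 fold changes in the 2 genotypes had a Pearson correlation of 0.895 and a Spearman correlation of 0.888. In cKO cells 8398 genes were called, 4171 higher and 4227 lower, and 1326 and 1842 of them changed at least 2-fold; on the TPM scale with 0.1 added the counts were 2583 and 3443.

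The Th2 cytokine genes Il5, Il13 and Il4 rose by 9.18 ± 0.31, 6.52 ± 0.44 and 4.19 ± 0.36 in cKO cells, to 1089 ± 311, 1718 ± 296 and 133 ± 40.2 CPM. All 24 cytokine and chemokine genes rose, with a median of 4.50, or 4.37 with genes at 0 counts set to their floor (camera adjusted p = 1.3e-25; adjusted p = 0.0055 with an estimated correlation). Il1a, Il3, Pdpn and Il2 were at least 776-fold, 756-fold, 197-fold and 200.4-fold higher than a floor of 3 counts over the 3 non-stimulated libraries. Pth rose 1912-fold (95% interval 654 to 9274) and the chemokine gene Cxcl2 315-fold (56.2 to 12457), from 3 counts and 1 count before stimulation. Tpbg and the scavenger receptor gene Olr1 rose by 8.04 ± 0.30 and 7.88 ± 0.31. Klf2 was lower by the same order as in control cells (-5.79 ± 0.42). Also lower were Krt80 (-6.62 ± 0.50), Igsf5 (-6.02 ± 0.60), Nhsl2 (-5.45 ± 0.52), Rap1gap2 (-5.37 ± 0.65), Pcyt1b (-4.63 ± 0.23), Rnf144a (-4.40 ± 0.35) and Endou (-4.40 ± 0.28). The values of Ifi203 (-5.12 ± 0.44) and Ifi206 (-4.57 ± 0.49) are uncertain, because these genes belong to a family of near-identical copies.

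In cKO cells 20 of 24 activation genes rose (median 1.79; camera adjusted p = 2.3e-15; adjusted p = 0.092 with an estimated correlation), including Egr3 (4.21 ± 0.17) and Bhlhe40 (2.67 ± 0.17). Of 12 inhibitory receptor genes 8 rose and 3 fell (adjusted p = 2.4e-06; 0.086 as adjusted p with an estimated correlation). The Th2 list had 8 higher and 3 lower of 15 (adjusted p = 0.0046, but adjusted p = 0.52 with an estimated correlation), and the unfolded protein response list 11 higher of 15 (adjusted p = 6.3e-04, but adjusted p = 0.45 with an estimated correlation). The ATF4 and amino acid list had 13 higher and 1 lower of 15 (adjusted p = 4.6e-05, but adjusted p = 0.45 with an estimated correlation). Among 15 quiescence genes 8 fell and 2 rose (adjusted p = 0.015), and 11 of 22 cell cycle genes fell (adjusted p = 0.011); with an estimated correlation their adjusted p was 0.45 and 0.63. Of 25 filamin and actin genes 14 fell and 1 rose (adjusted p = 0.0079, but adjusted p = 0.52 with an estimated correlation), including Flna (-0.74 ± 0.13). Sterol synthesis genes had 12 of 18 lower (adjusted p = 0.016, but adjusted p = 0.63 with an estimated correlation), and follicular helper genes 3 higher and 3 lower of 9 (adjusted p = 0.016, but adjusted p = 0.11 with an estimated correlation).

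The lists without a call at the preset correlation in cKO cells were Th1 (4 higher and 5 lower of 12), Th17 (3 and 1 of 6), regulatory T cell (6 and 2 of 10), glycolysis (3 and 3 of 15), interferon response (2 and 3 of 13), p53 and apoptosis (9 and 6 of 18), hypoxia (5 and 3 of 12), ASB2 ligase and substrates (5 and 4 of 13) and mitochondrially encoded genes (7 and 0 of 13). Their camera adjusted p ranged from 0.092 to 0.92. The 7 mitochondrially encoded genes that rose included mt-Co3 (0.73 ± 0.17) and mt-Co1 (0.67 ± 0.17), which had log2 fold changes of 0.51 and 0.44 without stimulated cKO replicate 3, the library with the highest values. Members were counted the same way when adjusted over the list alone in 18 of 27 lists in control cells (233 against 225 members called over all genes) and in 20 of 27 in cKO cells (238 against 235). Median, mean and test differed in sign for Th1 genes in both genotypes, for glycolysis in both, for hypoxia and interferon response in control cells, and for follicular helper and plasma cell genes in cKO cells. The signs of the glycolysis, hypoxia and cytotoxic medians in control cells and of the ASB2 ligase median in cKO cells turned on the TPM scale.

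**Figure D3:**
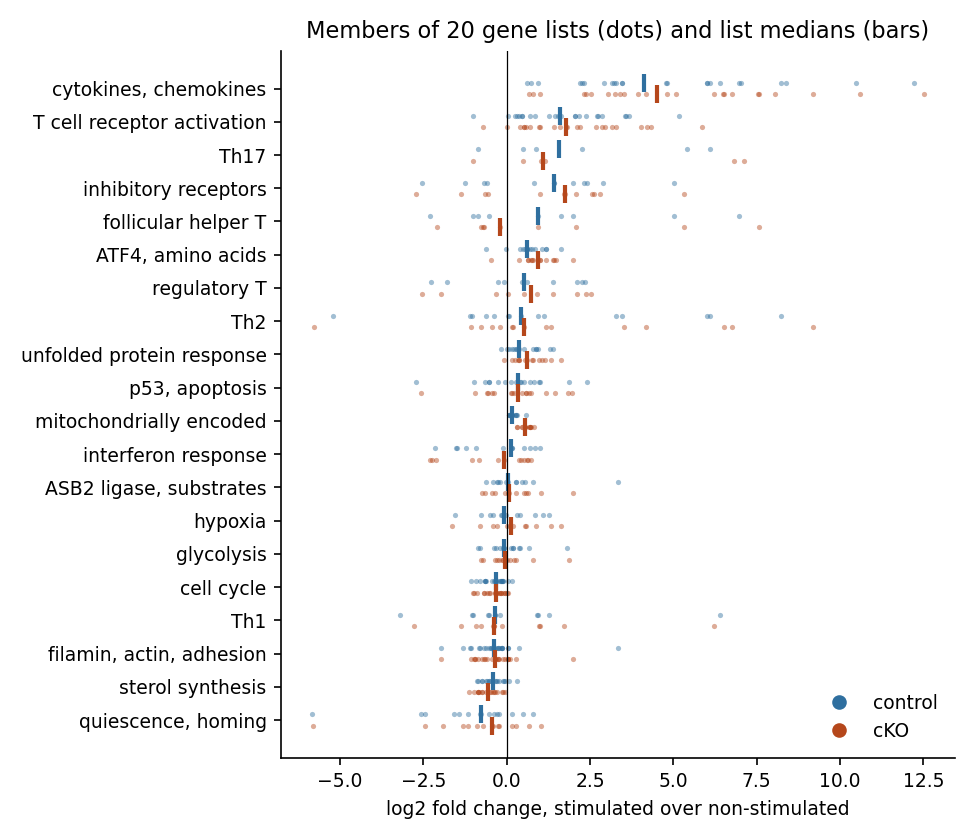
Log2 fold change after stimulation of each measured member (dots) of 20 gene lists, with the list median (bars), in control (blue) and cKO (red) cells; members with 0 counts before stimulation are drawn at their fitted values. Cytokine and chemokine genes have the highest medians, 4.11 and 4.50, and quiescence genes a median of -0.77 in control cells.

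Markers of cell types were measured in the same libraries. In the list of CD4 T cells, 1 of 10 genes rose and 5 fell in each genotype, and Cd28 was the most abundant, at 912 CPM in non-stimulated control cells. Cd5 rose by 1.35 ± 0.14 in control cells and by 1.37 ± 0.14 in cKO cells, and Cd3e changed by -0.78 ± 0.10 and -0.72 ± 0.10. Of 9 cytotoxic genes 1 fell in control and none in cKO cells; Gzmb was abundant in all groups, at up to 1892 CPM, and Gzma was at 244 ± 150.4 CPM in non-stimulated and 138 ± 91.1 CPM in stimulated control cells. Of 4 genes of gamma-delta T and natural killer cells 3 fell in each genotype, with Trdc at -1.14 ± 0.22 and Klrb1c at -3.26 ± 0.71 in control cells; Klrb1c has near-identical relatives that can share its reads. Of 7 B cell genes 2 fell in each genotype, and Ighm went from 69.8 ± 7.31 to 22.8 ± 6.27 CPM in control cells. Of 3 monocyte and macrophage genes 2 fell in each genotype, with Adgre1 at -3.70 ± 0.43 and Itgam at -3.06 ± 0.57 in control cells. In the dendritic list 3 of 6 genes rose, with Cd74 at 2.43 ± 0.34 in control cells, and 2 fell in control and 1 in cKO cells. Of 3 plasma cell genes Sdc1, which T cells can also express, rose by 4.21 ± 0.34 in control and 4.42 ± 0.35 in cKO cells, and 1 other fell in cKO cells. None of these 7 lists was called by camera in either genotype (adjusted p of at least 0.12). Lists with fewer than 3 tested genes are given by their most abundant gene, chosen after its values were seen: at most 8.14 CPM for neutrophil (Cxcr2), 7.32 for mast cell and basophil (Cpa3), 0.922 for erythroid and platelet (Itga2b) and 2.19 for stromal genes (Col1a1). In the endothelial list Pecam1, which T cells can also express, was at 184 CPM in non-stimulated cKO cells.

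The comparison of cKO with control cells after stimulation asked which RNAs differ in activated Th2 cells when Asb2 RNA is reduced, here to 28.3% of the control level. Asb2 itself was the only one of 15619 genes called by edgeR. The Th2 cytokine genes were at like levels in the 2 genotypes: Il4 was at 133 ± 40.2 CPM in cKO and 115 ± 21.3 CPM in control cells (log2 fold change 0.21 ± 0.26), and the changes were 0.07 ± 0.17 for Il5, -0.01 ± 0.28 for Il13 and 0.00 ± 0.10 for Gata3. The filamin gene Flna had a log2 fold change of -0.01 ± 0.12. These values are of RNA only, and protein levels of ASB2 and of the filamins were not measured here. At an unadjusted p under 0.05 there were 283 genes, or 1.81%, which is under the share of 0.05 expected if no gene differed. The number was 525 without stimulated cKO replicate 2, 523 without stimulated cKO replicate 4 and 576 with 7SL RNA as a covariate. It was 564 without a filter on low counts, where more genes were tested. A share under 0.05 does not show that the genotypes are alike, here or in the comparisons below. DESeq2 called 5 genes: Asb2, Myo7a (-0.73), A630091E08Rik (-0.76), Pgk1-rs7 and Gm15725. The last 4 were chosen after their values were seen, none was called by edgeR, and Pgk1-rs7 is a near-copy of Pgk1 that can share its reads. For Myo7a the cKO libraries lay below the control libraries after stimulation (3.26 to 4.79 against 6.12 to 7.87 CPM) and without it (3.54 to 4.33 against 5.45 to 5.94). The same held for A630091E08Rik (2.48 to 3.71 against 4.73 to 5.80, and 5.85 to 6.39 against 7.28 to 8.09). Neither was called without stimulation, and with DESeq2 Pgk1-rs7 had opposite signs in the 2 conditions. Of 13249 genes with at least 1 CPM on average, 95.2% had a 95% interval of the genotype change inside 2-fold in either direction.

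**Figure D4:**
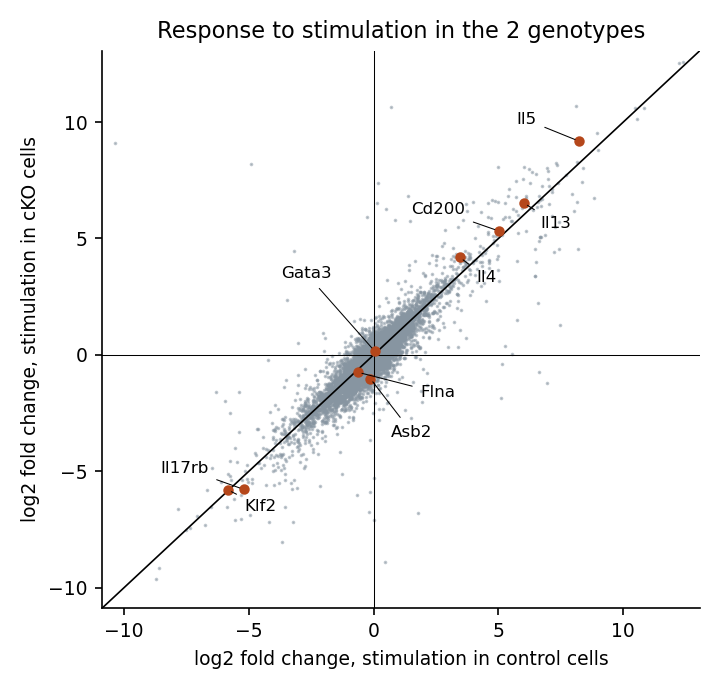
Log2 fold change after stimulation in control cells (horizontal axis) and in cKO cells (vertical axis) for each of 15619 genes (grey), with the line of equality and 9 genes marked. The response of most genes lies along the line (Pearson correlation 0.895 across genes), and Asb2 lies below it, at -0.13 in control and -1.01 in cKO cells.

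Of 27 lists, mitochondrially encoded genes were higher in stimulated cKO cells at the preset correlation (median 0.30, camera adjusted p = 7.6e-08), but the adjusted p was 0.95 with an estimated correlation. It was also 0.956 at the preset correlation without stimulated cKO replicate 3, the library with the highest mitochondrial share. No other list was called at that setting. A block for the replicate number added 6: quiescence, glycolysis, sterol synthesis, unfolded protein response, cytotoxic, and gamma-delta T and natural killer genes (camera adjusted p between 0.0230 and 0.0479). Whether that number pairs libraries was not settled. No member other than Itgam passed when adjusted over the list alone. Itgam, of the monocyte and macrophage list, was at 0.0390 ± 0.0511 CPM in cKO and 0.309 ± 0.274 CPM in control cells, with an unadjusted p of 0.012 by edgeR. Its list had only 3 tested genes, and the stimulated cKO libraries held 3 counts of it together. The libraries overlapped, at 0 to 0.108 CPM in cKO and 0.0506 to 0.613 CPM in control cells.

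Without stimulation, no gene was called between cKO and control cells by edgeR. At an unadjusted p under 0.05 there were 402 genes (2.57%), again under the share of 0.05 expected if no gene differed. That number was 1085 without control replicate 2 and 739 without cKO replicate 2 of the non-stimulated cells, and 774 with limma-voom. It was 668 without a filter on low counts, where more genes were tested. Il5 was at 1.88 ± 0.400 CPM in cKO and 3.43 ± 1.00 CPM in control cells (log2 fold change -0.88 ± 0.31, unadjusted p = 0.011), and Il4 and Il13 had changes of -0.53 ± 0.36 and -0.51 ± 0.37. Egr3 had a change of -0.53 ± 0.17 (unadjusted p = 0.0060), Gata3 of -0.12 ± 0.12 and Flna of 0.10 ± 0.14. limma-voom called 0 genes, limma on log2 TPM called 0 or 3 with 0.1 or 1 added, and DESeq2 called 4: Pagr1a (-3.69), Pgk1-rs7, Gm20236 and Gm42791. These were chosen after their values were seen and had at most 8.41 CPM in any group. Intervals inside 2-fold were found for 90.2% of 13249 genes.

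In the gene lists the same comparison had 5 calls at the preset correlation and none with an estimated one (lowest adjusted p = 0.75) or by fry (lowest adjusted p = 0.83), and no member was called. Genes of T cell receptor activation (median -0.20, camera adjusted p = 6.9e-05), ATF4 and amino acids (-0.19, adjusted p = 3.0e-06), Th2 (-0.18, adjusted p = 0.0020) and hypoxia (-0.13, adjusted p = 0.0050) were lower in cKO cells, and sterol synthesis genes were higher (0.16, adjusted p = 0.0020). On the TPM scale the hypoxia median was 0.08, against a shift of 0.15 in the median of all genes. Among cell types, 4 gamma-delta T and natural killer genes had a median of -0.57 and 9 cytotoxic genes one of -0.25, neither called (camera adjusted p = 0.10 and 0.29). Non-stimulated control replicate 3 had the highest Gzma, Eomes and Klrb1c of the 6 libraries (416, 99.2 and 17.8 CPM, against at most 366, 57.1 and 6.12). Each call rested on 1 or more libraries. Without non-stimulated control replicate 3 the adjusted p was above 0.05 for all but hypoxia, which was lost without control replicate 1 or cKO replicate 3. Without cKO replicate 1 the activation, Th2 and sterol calls were lost, and without cKO replicate 3 the Th2 and sterol calls; the adjusted p reached 0.753, 0.252, 0.656, 0.125 and 0.656 in the order above.

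The difference between the 2 stimulation responses was tested as an interaction, and edgeR called no gene. At an unadjusted p under 0.05 there were 605 genes (3.87%), also under the share of 0.05 expected if no gene differed. This number became 1130 without non-stimulated control replicate 2 and 403 without non-stimulated control replicate 3. It was 351 without the latter library and stimulated cKO replicate 3 together (a setting chosen after the result was seen). It was 958 without a filter on low counts, where more genes were tested. limma-voom called 0 genes, limma on log2 TPM called 0 or 2, and DESeq2 called 2, Pgk1-rs7 and Gm14308, chosen after their values were seen. Asb2 fell with stimulation in cKO cells (-1.01 ± 0.20; edgeR adjusted p = 4.5e-04) and was not called in control cells (-0.13 ± 0.18; edgeR adjusted p = 0.57), with an interaction of -0.88 ± 0.27 (unadjusted p = 0.0052, adjusted p = 0.997). The interaction was 0.95 ± 0.35 for Il5 (unadjusted p = 0.015) and 0.55 ± 0.21 for Egr3 (unadjusted p = 0.017), and neither was called. The interactions of Flna, Gata3, Il4 and Il13 were -0.12 ± 0.19, 0.13 ± 0.15, 0.74 ± 0.45 and 0.50 ± 0.46. Intervals inside 2-fold were found for 78.4% of 13249 genes, so smaller differences in response were less well resolved than the genotype comparisons. Gene lists had 8 calls at the preset correlation and none with an estimated one (lowest adjusted p = 0.77) or by fry (lowest adjusted p = 0.72).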

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

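The tests of residual Asb2 RNA, of the spread after stimulation alone and of 6 short RNAs together were chosen only after the result was seen; the others in this part were not, but the reading of the test with 1 surrogate variable was changed after its result was seen. Gaps of single libraries were examined in 236 sets of 4 or 5 stimulated libraries, 16 stood out, and chance alone gives about 11.8.

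Asb2 RNA did not vanish in cKO cells, and its remainder was a smaller share of control after stimulation: the interaction had an unadjusted p of 0.00517 (edgeR adjusted p = 0.997 over all genes), with a log2 value of -0.88. The same share of T cells with an intact gene in both conditions would make the ratio of cKO to control equal in both. This holds only if cells with a deleted gene give no Asb2 reads. On that condition an interaction of this size counts against an equal share (highest unadjusted edgeR p of 0.0203 without each library in turn). If transcripts with undeleted exons remain in those cells, the interaction cannot decide the question. It is also the interaction that drew attention and not a further test, so the evidence is weak. Counting on an annotated transcript of clearly different length is argued against. The relative effective length of Asb2 differed between genotypes by -2.66% without stimulation and by -0.587% after it (exact permutation p = 0.66). Without stimulation the cKO libraries all lay below the control libraries, at 0.996 to 1.015 against 1.023 to 1.042. The exact permutation p of 0.1 was the smallest possible there, so a small difference in length is not excluded. Transcripts that keep the undeleted exons, and a share of cells with intact Asb2 that falls under stimulation, remain open and were not tested.

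Asb2 was the only gene called by edgeR between genotypes after stimulation (5 called by DESeq2). Spread between stimulated libraries too wide to set 2-fold changes apart gene by gene is argued against. After stimulation 95.2% of unadjusted 95% intervals lay inside 2-fold, against a bound of 90%. Over both conditions the lower share was 90.2%, without stimulation. It passed that bound by less than its spread but was far above the 50% that this explanation would need. The intervals do not show that a 2-fold change would have been called, because calls were adjusted over 15619 genes. Asb2 without stimulation, with a log2 fold change of -0.94, was not called. Variation between libraries unrelated to genotype that hides calls cannot be told apart: 1 gene was called with 1 surrogate variable, which met the bound of 3 or fewer set beforehand against it, but that bound was set aside afterwards, because a split of the same libraries called 213 genes and so showed variation between them that can yield calls. Of 100 splits of the 9 stimulated libraries drawn from 126, 16 called at least 1 gene, so that chance cannot be excluded for a count of 1 gene of any name. The split with 213 set replicates 1 and 3 of both genotypes against the rest. These were the only stimulated libraries with positive scores on the third principal component. Their 7SL RNA took 1.82% to 2.57% of counts, but stimulated control replicate 2, at 2.01%, lay on the other side. The split points to a structure of the samples of untested source. The call of Asb2, a gene named beforehand, does not rest on that count: its libraries did not overlap between genotypes, with an exact permutation p of 0.00794.

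Without stimulation and for the interaction the real split called 0 genes by edgeR (402 and 605 at an unadjusted p under 0.05; 4 and 2 called by DESeq2). The unadjusted numbers moved to 1085 and 1130 without non-stimulated control replicate 2, the first to 739 without non-stimulated cKO replicate 2 and the second to 403 without non-stimulated control replicate 3. Any split calls at least as many as 0, so the 10 of 10 and 100 of 100 splits that did so say nothing about chance, and 10 splits are also too few for a share under 0.05. The highest other splits called 219 and 192 genes, which again points to a structure of the samples of untested source. For stimulation, chance can be excluded. Each split was fitted to the libraries compared alone, over the genes kept for all 15 libraries. The real counts therefore differ from those of the model with all 15 libraries. They also differ from the alternative with only the groups compared, where the filter was redone (7564 in control and 7714 in cKO cells). In control cells 1 of 56 splits, the real one, called as many genes (7742, highest other 2), and in cKO cells 1 of 35 (7888, highest other 1).

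The 7SL RNA, a short RNA without a poly(A) tail, took 0.900% to 2.57% of counts in stimulated libraries, with 4 libraries at 1.22% or less and 5 at 1.82% or more. The lower and the higher libraries each included both genotypes, which argues against genotype of the cells as the source of that division. The difference of -0.08 in log2 CPM between genotypes was smaller than the SD of either (0.69 and 0.51; exact permutation p = 0.817). That met the bound set against genotype. With 4 against 5 libraries and this spread, an added effect of genotype is not excluded. Library size cannot be told apart, because 9 libraries give a Pearson r of 0.0369 (exact permutation p = 0.931, r = 0.387 without the 2 libraries farthest from the median) and Spearman rho of 0.0833 (exact permutation p = 0.843). Short non-polyadenylated RNAs may have been retained to a different degree in each library: the median Spearman rho over 15 pairs of 6 such RNAs was 0.700 (median Pearson r 0.696, or 0.699 without 2 libraries), and 6 pairs had an exact permutation p under 0.05 after adjustment over 16 relations. Of these RNAs 2 are copies of 7SL RNA (rho 0.967), so the pairs are not all separate relations. The pairs that passed were the 2 copies with each other, each copy with the same 2 other RNAs, and a pair without 7SL RNA. Neither copy passed with the remaining 2 RNAs (adjusted exact permutation p of 0.086 to 0.11). A change in the cells themselves remains open.

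In stimulated cKO replicate 3 the 10 most abundant genes took 12.8% of counts against 8.48% to 9.22% in the other libraries of the group (gap over range 0.830). The same library stood out for Hspa5 (1735 CPM against 1040.5 to 1152; 0.840), Calr (826 against 680.5 to 697; 0.889) and Klrb1c (1.97 against 0.243 to 0.376; 0.923). Stimulated cKO replicate 4 stood out for Tnfsf11 (82.4 CPM against 129.7 to 136; 0.885), Fos (13.0 against 15.8 to 16.3; 0.840), Gpr83 (14.4 against 16.9 to 17.4; 0.843) and Jak2 (1637 against 1348 to 1369.7; 0.924). Stimulated cKO replicate 1 stood out for Mcm6 (283 CPM against 257 to 261; 0.839) and Coro1a (237 against 162 to 165; 0.958), and replicate 2 for Lrrc32 (1.35 against 1.99 to 2.10; 0.855). Stimulated control replicate 4 stood out for Eomes (13.0 CPM against 3.85 to 6.13; 0.751), Igsf5 (0.446 against 0 to 0.116; 0.741), Cd3e (246 against 188 to 203; 0.731) and Gzma (300.5 against 85.6 to 104; 0.916). In stimulated control replicate 2, Il21 was at 238 CPM against 170.1 to 176 in the other libraries (0.919).

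Between genotypes, 8 lists responded differently to stimulation at the preset correlation of camera, none with an estimated correlation (adjusted p of at least 0.77). The adjusted p was 5.5e-04 for T cell receptor activation (median interaction 0.25), for ATF4 and amino acid genes (0.22) and for mitochondrially encoded genes (0.39), 0.0134 for Th2 (0.19), 0.0195 for quiescence (0.13), sterol synthesis (-0.15) and hypoxia (0.18), and 0.0496 for 3 plasma cell genes (-3.04). On the TPM scale with 0.1 added, the medians of Th2, quiescence, ATF4 and hypoxia genes were -0.04, -0.10, -0.01 and -0.12, against a shift of -0.23 in the median of all genes. Leaving out non-stimulated control replicate 3 ended the activation, ATF4, Th2 and sterol calls, and leaving out stimulated cKO replicate 3 ended those for mitochondrially encoded, quiescence, sterol and plasma cell genes. Non-stimulated cKO replicate 1 ended the activation, ATF4, Th2, sterol and plasma cell calls, and the hypoxia call ended without any 1 of 4 libraries. Across all single libraries left out, the highest adjusted p was 0.494, 0.261, 0.333, 0.466, 0.677, 0.590, 0.151 and 0.303 in the order of the lists above.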

How the results depend on the processing

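The 7SL covariate and leaving out 2 libraries together were chosen only after the result was seen; the other alternatives were not. The counts for stimulation kept their size within 1.5-fold under each alternative run, from 5823 (log2 of TPM plus 1) to 8701 (limma-voom) genes in control and from 6014 to 8879 in cKO cells; without each library in turn they ran from 6682 to 8076 and from 7428 to 8506. The share that rose changed most on the TPM scale, to 64.0% in control and 42.9% in cKO cells with 0.1 added and 63.6% and 42.0% with 1 added. With 0.1 added the median of all genes moved by 0.14 in control and -0.09 in cKO cells, 0.15 and -0.07 between genotypes without and after stimulation, and -0.23 in the interaction. Without stimulation, 0 genes were called between genotypes by edgeR (402 at an unadjusted p under 0.05, but 1085 without non-stimulated control replicate 2, 739 without non-stimulated cKO replicate 2, 774 with limma-voom and 668 without a filter), against 4 with DESeq2, 3 with log2 of TPM plus 1, and 1 each without a filter (Gm42791), with 1 surrogate variable (Gm20431), and without non-stimulated control replicate 3 and stimulated cKO replicate 3 together (Pagr1a); without each library in turn the count was 0 to 1. The single call came without stimulated cKO replicate 3 (Gm42791) or without non-stimulated control replicate 3 (Pagr1a). After stimulation the count was 1, Asb2, under each alternative and without each library (1 to 1), except 5 with DESeq2; the 283 genes at an unadjusted p under 0.05 became 576 with the 7SL covariate, 564 without a filter, and 525 and 523 without stimulated cKO replicates 2 and 4. For the interaction the count of 0 by edgeR (605 at an unadjusted p under 0.05, 1130 and 403 without non-stimulated control replicates 2 and 3, 351 without the latter and stimulated cKO replicate 3 together and 958 without a filter) became 2 with DESeq2, 2 with log2 of TPM plus 1 and 1 with the block within genotype (Pgk1-rs7), and stayed 0 without each library; only the compared groups is the same model there. Without a filter more genes were tested, so its numbers at an unadjusted p under 0.05 are not out of the same total. The cause of these differences was not tested. The log2 fold change of Asb2 after stimulation ran from -1.84 to -1.76 without each library, with adjusted p between 1.04e-05 and 0.00736, and without stimulation from -1.14 to -0.66, with no adjusted p under 0.05. For stimulation, no called change of a named gene turned direction under the alternatives run: in control cells 3661 results kept their side of the threshold, 24 lost and 27 gained a call, and in cKO cells 3660 kept it, 29 lost and 23 gained one, with Tyrobp (control) and Igkc (cKO) among those losing it most often. Between genotypes small values turned sign, such as Flna (-0.09 to 0.06) and Il13 (-0.11 to 0.09) after stimulation over the alternatives. Of 27 lists, an estimated correlation ended 9 calls in control and 10 in cKO cells, 5 and 1 between genotypes without and after stimulation, and 8 in the interaction; fry called 9 and 11 more lists for stimulation and none between genotypes, and the replicate block added 6 calls between genotypes after stimulation, and in the interaction added the unfolded protein response (adjusted p = 0.038) and ended hypoxia (adjusted p = 0.071). Small changes are missed at this depth and group size: in simulated data 33.3% and 52.2% of 1.5-fold and 75.1% and 84.1% of 2-fold genotype changes were recovered without and after stimulation. The simulated sets held many changed genes at once, so in a comparison with few calls more changes can be missed.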

Other observations

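The gene families of this part were chosen only after the result was seen; the test of genes next to Asb2 was not. Ligands of the tumour necrosis factor family rose with stimulation, 10 of 13 in control and 9 of 13 in cKO cells, with 2 lower in each and medians of 1.99 and 1.78 (camera adjusted p of 9.6e-06 and 9.2e-06 over the families; adjusted p of 0.0078 and 0.016 with an estimated correlation). Tnfsf8, the ligand of CD30, went from 61.2 ± 4.47 to 901 ± 65.9 CPM in control cells (log2 fold change 3.88 ± 0.15) and rose by 4.19 ± 0.15 in cKO cells. Tnf rose by 2.32 ± 0.17 and 2.38 ± 0.17, while Tnfsf13b, the gene of the B cell factor BAFF, changed by -2.34 ± 0.23 and -2.65 ± 0.25.

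Families of the protein synthesis and turnover machinery rose with stimulation at the preset correlation, except cytosolic ribosomal proteins and tRNA synthetases in 1 genotype each. The 84 cytosolic ribosomal proteins, called in cKO but not in control cells, had medians of 0.04 in control and 0.26 in cKO cells (9 and 27 higher, 1 lower in each; camera adjusted p of 0.53 and 0.017, and 0.94 and 0.79 with an estimated correlation). All 8 subunits of the cytosolic chaperonin rose in both genotypes, with medians of 0.71 and 0.81 and Cct6a at 0.85 ± 0.10 and 0.98 ± 0.10 (adjusted p of 0.42 and 0.46 with an estimated correlation). Of 77 mitochondrial ribosomal proteins 47 rose in control cells and 49 in cKO cells, of 41 proteasome subunits 30 and 29, of 18 tRNA synthetases 10 and 9 (a family not called in cKO cells), and of 52 translation initiation factors 34 and 38 (adjusted p of 0.51 in control and 0.48 in cKO cells for each of these families with an estimated correlation). Of 8 GTPases of the Gimap family 6 fell in control and 7 in cKO cells (adjusted p of 0.37 and 0.44 with an estimated correlation), with Gimap7 at -1.34 ± 0.10 and -1.07 ± 0.11 and Gimap4 at -1.12 ± 0.11 and -1.07 ± 0.11. Of 29 kinesins 13 and 16 fell (adjusted p of 0.45 and 0.48 with an estimated correlation).

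Between genotypes without stimulation, 13 Krüppel-like factor genes had a median log2 fold change of -0.22 in cKO cells (camera adjusted p = 4.5e-04), but none was called by edgeR, 2 had an unadjusted p under 0.05 (Klf9, -0.39 ± 0.15; Klf10, -0.41 ± 0.19), and the adjusted p was 0.0603 with an estimated correlation and 0.147 by fry. On the TPM scale with 0.1 added the median was -0.06, but there the median of all genes moved up by 0.15, so the family stayed below it by about as much. After stimulation the family median was 0.11 (camera adjusted p = 0.36), and the interaction was 0.24 (camera adjusted p = 0.0013; adjusted p = 0.11 with an estimated correlation). Of the 20 families, camera at the preset correlation called 2 between genotypes without stimulation, 3 after it and 5 in the interaction, and none with an estimated correlation. The others were cytosolic ribosomal proteins in all 3 comparisons (medians of -0.07, 0.11 and 0.19; on the TPM scale 0.08, 0.03 and -0.07), mitochondrial ribosomal proteins (0.04 and 0.08) after stimulation and in the interaction, complex I subunits (0.08) after stimulation, and translation initiation factors (0.10) and dual-specificity phosphatases (0.22) in the interaction. Of the last 4 families, the medians of all but complex I turned sign on the TPM scale, where the median of all genes moved by -0.07 after stimulation and -0.23 in the interaction.

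A segment of another strain's genome carried with the modified allele could alter genes next to Asb2. Of the 20 tested genes nearest to it in the order of the GRCm38 assembly, 0 without stimulation and 1 after it had an unadjusted p under 0.05 (Dicer1, -0.16), with a median of 0 and a 95th percentile of 2 in 10000 random sets of 20 genes. With 1 such gene the flanking genome of another strain is neither supported nor excluded.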
